A study of Mus musculus with 4 samples.

How the data were processed

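Gene expression was measured in 4 RNA samples of Hepa1c1c7, a mouse hepatoma cell line, of which 2 came from cells given 100 µM diethyl maleate (DEM) and 2 from cells given the solvent dimethyl sulfoxide (DMSO), each for 6 hours. DEM is an electrophile that reacts with thiols such as glutathione. Group and replicate number were taken from the sample titles. The design text calls the samples of a group independent RNA samples and does not say that they came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The extract protocol in the labels speaks of liver tissue although every other label names the cell line, and the samples were treated here as cell line samples.

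Per the labels' protocols, 500 ng of total RNA was amplified, labelled with Cy3 and hybridised in 1 colour. Per the file headers, the arrays were of an Agilent mouse design annotated on mm9 and were read with Agilent Feature Extraction 10.7.3.1 under the protocol GE1_107_Sep09, and all 4 lay on 1 slide with 1 scan time, so slide and scan could not be tested as batches. The values used are the processed signals of each spot, an intensity on a linear scale that per the file headers comes from Feature Extraction after its own background subtraction, together with its outlier, saturation and well-above-background flags. The value table of the series held the same intensity, with all 45018 spots of each array equal to the processed signal, and the authors' deposited columns had medians from 13.8 to 16.2. Its scale is therefore linear and uncentred, and using it changed nothing.

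From these values, log2 of the processed signal was taken and the 75th percentile over the 43379 non-control spots of the same array was subtracted. Spots with an outlier flag were dropped, the spots of a probe were averaged, and 22 of 41174 probes that had no unflagged spot on an array were left out. A probe was tested if it was well above background on at least 2 of the 4 arrays. The arrays name probes by accession. Through an NCBI RefSeq table of assembly GRCm38.p6, used for names alone because the array annotation is on another build, 26690 probes received 1 symbol, covering 18217 symbols, and 14484 kept the name in the files. Where several probes named the same gene, the one with the highest mean over the 4 arrays was used. This left 15537 genes tested, 10956 with a symbol and 4581 under an accession or probe name. Coordinates are not given, since no genome of the array's build was used here.

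The comparison of DEM with DMSO was a linear model fitted across all genes with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene with no probe well above background on any array of a group has only a bound there: its fold is given as "at least", from the bright group's mean against, per dim array, the higher of the lowest signal among probes well above background and the probe's own. The 26 gene lists were tested with limma's camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Replacing dim genes by their bounds changed the 2-decimal median of 0 of the 26 lists.

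Genes are named by a rule with several parts. It takes the 10 largest rises and the 10 largest falls among genes past the threshold, well above background on all 4 arrays and carrying a symbol that is not a clone or transcript name, for which 1 rise and 1 fall were passed over. It adds up to 3 called members of each list, or the member with the largest change where none was called, and the genes Nqo1, Hmox1, Gclc, Gclm, Txnrd1, Srxn1, Slc7a11, Nfe2l2 and Keap1. It ends with the 5 largest bounded changes. This rule, the lists, the design and the alternatives were fixed before the data were examined. Alternatives were normexp background correction, quantile normalization, median scaling, the value table, no filter on dim probes, a filter on all 4 arrays, every probe on its own, the mean of a gene's probes, eBayes with an intensity trend with and without robust fitting, the replicate number as a block, and leaving out each array. Normexp used the median spot signal with the median background and an offset of 50, in place of the mean spot signal planned, because the compact set of columns used here holds no mean signal. Scaling on spike-in probes was added after seeing the data.

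The fit was tested on simulated data built from the gene means and the fitted prior spread of these arrays. In 20 simulated sets of 2 against 2 arrays with the 15537 genes of the comparison of DEM with DMSO, drawn independently per gene, 200 genes were changed. The fit recovered 43.3% of genes changed 2-fold and 89.3% of those changed 4-fold, and 5.11% of its calls were false. A list of 20 genes shifted by 0.50 on the log2 scale was called by camera at an unadjusted p under 0.05 in 20 sets, and an unshifted list of 20 genes in 0. Genes drawn independently from the fitted spread cannot show how camera or the share of false calls behaves when genes are correlated. The simulated spread also followed the model that the fit assumes, with no trend by signal. On the real arrays an intensity trend moved the calls to 415 higher and 311 lower. The recovered and false shares therefore need not hold for the real data. In 1 further set with no change, 0 genes were called. For arrays, the number of arrays limits the precision: with 2 per group, the median standard error of a log2 change was 0.11. The gene with probes of opposite sign is not reported here.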

Results

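Messenger RNA levels were measured on 4 arrays of Hepa1c1c7 mouse hepatoma cells, 2 from cells exposed to 100 µM DEM for 6 hours and 2 from cells exposed to DMSO. The series title describes DEM as activating NRF2, the transcription factor that drives antioxidant and detoxification genes, and the comparison asks which transcripts differ after exposure. On each array 20744 to 21659 of 41174 probes (50.4% to 52.6%) were well above background, and 0 spots were saturated. Across the 15537 genes tested, arrays of the same group correlated at r = 0.9942 for DEM and 0.9940 for DMSO, and arrays of different groups at 0.9893 to 0.9910. These correlations are across genes, which are not independent replicates.

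The genes called higher in cells exposed to DEM include ones that import cystine, make glutathione, conjugate electrophiles and break down haem, and those called lower include ones for chemokines and inhibitors of NF-kB. Slc7a11, the cystine importer that supplies cysteine for glutathione, was 35.5-fold higher (log2 change 5.15 ± 0.13, SE, n = 2 arrays per group), and Hmox1, which breaks down haem, was 23.4-fold higher (4.55 ± 0.13). The chemokine gene Ccl7 was 4.53-fold lower in DEM (log2 change −2.18 ± 0.19) and the chemokine gene Cxcl10 was 3.13-fold lower (−1.64 ± 0.12). In all, 111 genes were higher and 79 were lower in DEM at an adjusted p under 0.05 (limma, Benjamini-Hochberg), of which 83 and 53 changed at least 2-fold. For 190 of these 190 genes the values of the DEM arrays did not overlap those of the DMSO arrays, as held for 50.6% of all genes tested and would hold for 33.3% by chance. Rises made up 58.4% of the calls, against 71.3% when arrays were scaled on their median, which moved the median change of all genes from −0.01 to 0.14 on the log2 scale, and 34.9% when scaled on spike-in probes, a setting chosen after seeing the data. Without DMSO replicate 1 limma called 0 genes (983 higher and 1130 lower at an unadjusted p under 0.05). Without DMSO replicate 2 limma also called 0 genes (844 higher and 1171 lower at an unadjusted p under 0.05). Without DEM replicate 1 it called 69 higher and 52 lower, and without DEM replicate 2 it called 64 higher and 38 lower.

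**Figure D1:**
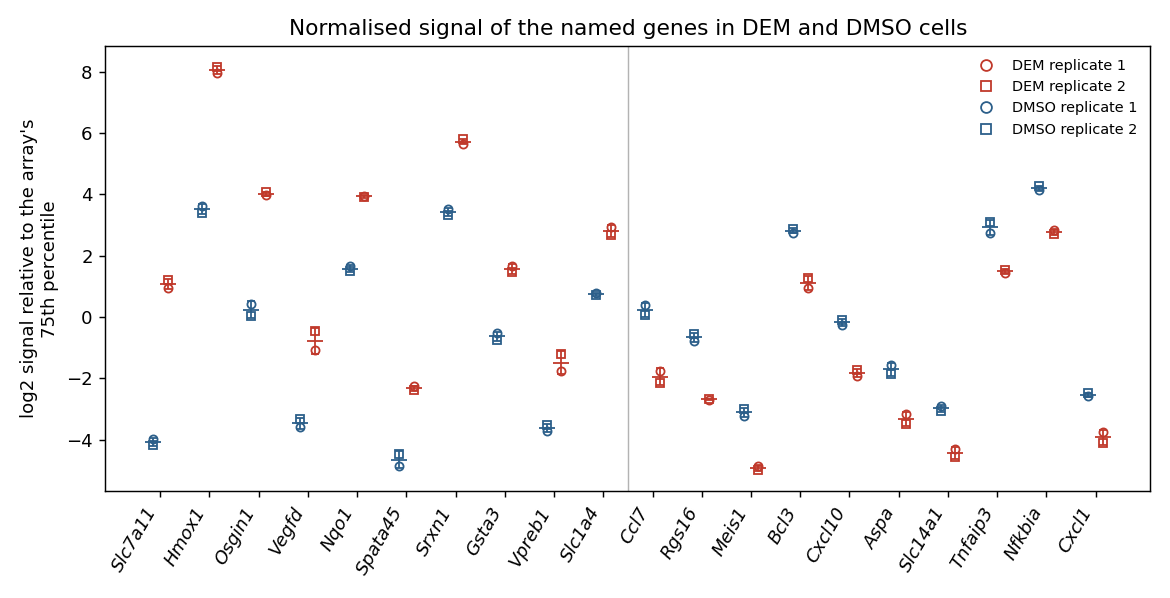
Normalised log2 signal (y axis, relative to the array's 75th percentile) of the 10 named genes with the largest rises and the 10 with the largest falls (x axis) on each of the 4 arrays. Circles are replicate 1 and squares replicate 2, DEM is red and DMSO blue, and the bars show the mean and SD of the 2 arrays of a group; Slc7a11 lies at −4.07 in DMSO and 1.07 in DEM, and Ccl7 at 0.23 in DMSO and −1.95 in DEM.

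Among the genes with the largest rises, Osgin1, a growth inhibitor induced by oxidative stress, was 13.8-fold higher (log2 change 3.78 ± 0.16). Nqo1, which reduces quinones, was 5.10-fold higher. Srxn1, which repairs oxidised peroxiredoxins, was 4.94-fold higher. Gsta3, a glutathione transferase, was 4.58-fold higher. Vegfd, a growth factor for lymphatic vessels, was 6.48-fold higher, and Spata45 was 5.02-fold higher. Vpreb1, known as part of the surrogate light chain of pre-B cells, was 4.37-fold higher, and Slc1a4, a neutral amino acid transporter, was 4.20-fold higher. The limma adjusted p (Benjamini-Hochberg) of these 8 genes and of Slc7a11 and Hmox1 lay between 0.00442 and 0.0436. The other probes of Slc7a11 that were also tested gave log2 changes of 3.82 and 4.58. Those of Srxn1 gave 1.90 and 1.79, against 2.30 for the probe used. The other tested probe gave 3.91 for Osgin1, 2.14 for Gsta3 and 1.82 for Slc1a4. After normexp, whose offset shrinks the changes of dim genes by construction, the log2 change was 3.73 for Slc7a11 and 1.66 for Vegfd. It was 0.91 for Spata45 and 1.21 for Vpreb1, and each of these genes stayed called.

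Among the genes with the largest falls, Rgs16, which shortens G protein signals, fell by 2.02 on the log2 scale, and Meis1, a homeobox transcription factor, fell by 1.82. Bcl3, an NF-kB cofactor of the IkB family, fell by 1.70. Tnfaip3, an enzyme that restrains NF-kB signalling, and Nfkbia, the IkB protein that holds NF-kB in the cytoplasm, each fell by 1.43. Cxcl1, a chemokine for neutrophils, fell by 1.39. Aspa, which cleaves N-acetylaspartate, fell by 1.63, and Slc14a1, a urea transporter, fell by 1.46. The limma adjusted p (Benjamini-Hochberg) of these 8 genes and of Ccl7 and Cxcl10 lay between 0.0229 and 0.0474. After normexp the log2 change was −0.68 for Meis1, −1.03 for Aspa, −0.61 for Slc14a1 and −0.70 for Cxcl1, and all 4 stayed called. With every probe on its own, the other probe of Aspa gave −1.32 and was not called (limma adjusted p = 0.0798). The other probe of Ccl7 gave −2.31 and was called (limma adjusted p = 0.0447).

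Genes of glutathione synthesis and cysteine uptake rose as a group. Of 13 tested, 5 rose, 0 fell and 8 were not called over all genes tested, and 8 rose when adjusted over the list alone. Besides Slc7a11, the rises were in Gclm and Gclc, the subunits of the enzyme that sets the rate of glutathione synthesis (4.02-fold and 2.18-fold), in Slc6a9, a glycine transporter (4.04-fold), and in Gsr, which regenerates reduced glutathione (2.03-fold, named after its value was seen). The list's median log2 change was 0.57 (range 0.46 to 0.72 over the alternatives, camera adjusted p = 2.97e-06, and adjusted p = 0.504 with an estimated correlation). Phase II conjugation and carbonyl reduction had 6 rises, 0 falls and 26 genes not called among 32, with 16 rises when adjusted over the list alone. Its median was 0.38 (range 0.28 to 0.53, camera adjusted p = 2.50e-09, and adjusted p = 0.504 with an estimated correlation). Gsta1 and Gsta2, glutathione transferases of the alpha class, were not well above background on either DMSO array and were at least 10.8-fold and 4.15-fold higher in DEM (limma adjusted p = 0.00442 and 0.0335). Their log2 changes after normexp were 1.46 and 0.79. These are close paralogs, and signal shared between their probes was not tested.

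Haem and iron genes rose as a group, with 4 rises, 0 falls and 12 not called among 16, and 10 rises when adjusted over the list alone. The rises were in Hmox1, in Slc40a1, the iron exporter ferroportin (3.25-fold), in Slc48a1, a haem transporter (2.55-fold), and in Alas1, the first enzyme of haem synthesis (1.75-fold, named after its value was seen). The median was 0.37 (range 0.29 to 0.51 over the alternatives, camera adjusted p = 3.45e-06, and adjusted p = 0.504 with an estimated correlation). The other tested probe of Slc48a1 gave a log2 change of 0.96, against 1.35 for the probe used. Genes that make NADPH also rose as a group, with 2 rises, 0 falls and 8 not called among 10, and 5 rises when adjusted over the list alone. Pgd, of the pentose phosphate pathway, was 2.49-fold higher and Idh1, the cytosolic isocitrate dehydrogenase, 2.20-fold higher. The median was 0.29 (range 0.22 to 0.44, camera adjusted p = 4.66e-04, and adjusted p = 0.504 with an estimated correlation).

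The thioredoxin and peroxiredoxin list was not called (median 0.02, range −0.05 to 0.17 over the alternatives, camera adjusted p = 0.152). Of its 15 genes, Srxn1 and Txnrd1, the cytosolic thioredoxin reductase (1.76-fold), rose, 0 fell and 13 were not called, with 2 rises when adjusted over the list alone. Of 8 ABC efflux transporters, Abcc4, an exporter of organic anions, rose 2.31-fold, 0 fell and 7 were not called, with 1 rise when adjusted over the list alone (median 0.01, range −0.07 to 0.15, camera adjusted p = 0.256). With every probe on its own, the other probe of Abcc4 had a log2 change of 1.20 and was not called (limma adjusted p = 0.0742). Nfe2l2, which encodes NRF2, had a log2 change of 0.05 ± 0.10 (limma adjusted p = 0.845), and its sign turned to −0.00 under quantile normalization and −0.03 under spike-in scaling and without DEM replicate 2. Keap1, the protein that targets NRF2 for degradation, had a log2 change of 0.53 ± 0.10 (limma adjusted p = 0.105). Sqstm1, an autophagy receptor that binds KEAP1, rose 2.17-fold and was the 1 call among 14 genes of NRF2 and its regulators, with 5 rises when adjusted over the list alone and 13 not called over all genes (median 0.05, range −0.02 to 0.20 over the alternatives; camera adjusted p = 0.0501, and 0.0367 without DEM replicate 2).

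**Figure D2:**
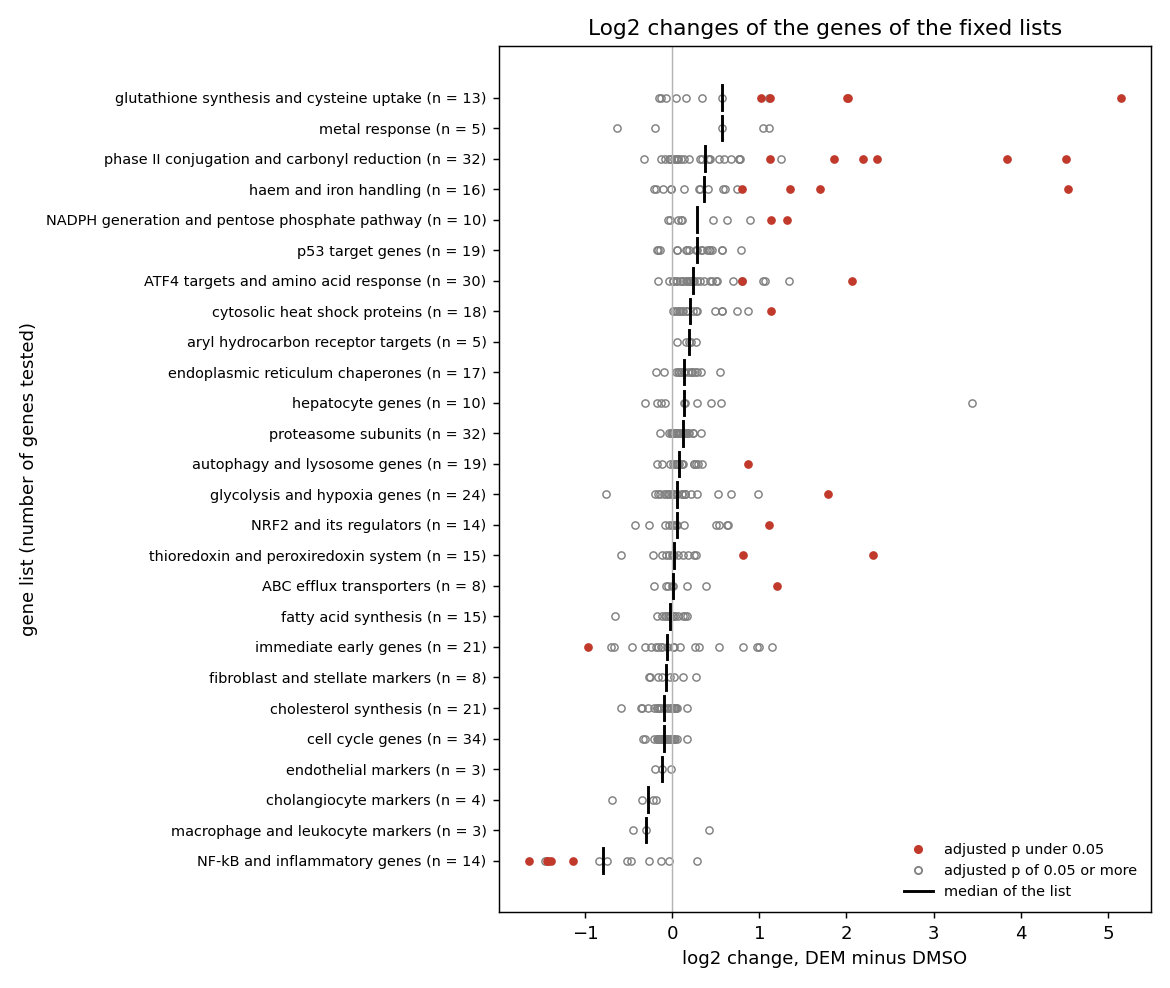
Log2 change, DEM minus DMSO (x axis), of each tested gene of the 26 lists (y axis, with the number of genes tested), from 2 arrays per group. Filled red points are genes past an adjusted p of 0.05, open points are the others and black bars are list medians, which run from −0.79 for NF-kB and inflammatory genes to 0.57 for glutathione synthesis and cysteine uptake.

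NF-kB and inflammatory genes fell as a group. Of 14 tested, 5 fell, 0 rose and 9 were not called, and 11 fell and 1 rose when adjusted over the list alone. The falls were in Cxcl10, Tnfaip3, Nfkbia, Cxcl1 and, named after its value was seen, Ccl2, a chemokine for monocytes, which fell by 1.14. The median log2 change was −0.79 (range −0.89 to −0.50 over the alternatives, camera adjusted p = 7.02e-08, and adjusted p = 0.504 with an estimated correlation). Of the macrophage and leukocyte markers 3 were tested and 0 were called (2 lower at an unadjusted p under 0.05, 0 adjusted over the list alone), with a median of −0.30 (range −0.39 to 0.06 over the alternatives, camera adjusted p = 0.346). Cd14 among them, a receptor for bacterial lipopolysaccharide, had a log2 change of −0.45 ± 0.12.

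ATF4 targets rose as a group (median 0.25, camera adjusted p = 3.59e-07, and adjusted p = 0.580 with an estimated correlation): 2 of 30 rose, Slc1a4 and Sesn2, a sestrin (1.74-fold), 0 fell and 28 were not called, with 7 rises when adjusted over the list alone. Cytosolic heat shock proteins rose as a group (median 0.21, camera adjusted p = 2.97e-06, and adjusted p = 0.504 with an estimated correlation): Dnajb4, a co-chaperone, was the 1 rise of 18 (2.19-fold), 0 fell and 17 were not called, with 6 rises when adjusted over the list alone. Autophagy and lysosome genes were shifted upward as a list by camera (median 0.08, camera adjusted p = 0.0252, and adjusted p = 0.593 with an estimated correlation). Under spike-in scaling the list was not called (median 0.00026, camera adjusted p = 0.159). The ubiquitin-like protein gene Gabarapl1 was the 1 rise of 19 (1.84-fold), with 0 falls, 18 not called and 1 rise when adjusted over the list alone. The median of ATF4 targets was 0.40 without DEM replicate 1 and 0.12 without DEM replicate 2, and that of heat shock proteins 0.13 without DEM replicate 2. The autophagy median was 0.17 without DEM replicate 2, 0.18 without DMSO replicate 1 and 0.0033 without DMSO replicate 2. The autophagy list lost its call without DEM replicate 1 (camera adjusted p = 0.248) or DMSO replicate 2 (0.223).

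Proteasome subunits, chaperones of the endoplasmic reticulum and p53 targets were shifted upward as lists by camera with 0 members called by limma over all genes. The proteasome median was 0.13 over 32 genes (3 higher at an unadjusted p under 0.05, 0 adjusted over the list alone; camera adjusted p = 0.00266, and adjusted p = 0.593 with an estimated correlation), and Psmd7, a subunit of the 19S lid, had a log2 change of 0.33 ± 0.08. The chaperone median was 0.14 over 17 genes (2 higher at an unadjusted p under 0.05, 0 adjusted over the list alone; camera adjusted p = 0.00797, and adjusted p = 0.504 with an estimated correlation), and Dnajb9 had a log2 change of 0.55 ± 0.14. The median of p53 targets was 0.29 over 19 genes (9 higher at an unadjusted p under 0.05, 1 adjusted over the list alone; camera adjusted p = 2.83e-04, and adjusted p = 0.504 with an estimated correlation), and Cdkn1a, which blocks the cell cycle, had a log2 change of 0.79 ± 0.10 (limma adjusted p = 0.0541). Without DMSO replicate 2 the proteasome list was not called (median 0.055, camera adjusted p = 0.101). The median of p53 targets was 0.13 without DEM replicate 2 and 0.19 without DMSO replicate 1. The chaperone median ran from 0.067 to 0.29 over the alternatives.

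Immediate early genes went both ways (median −0.06, range −0.16 to 0.09 over the alternatives, mean 0.06, camera adjusted p = 0.586): Junb, an AP-1 subunit, fell by 0.97 and was the 1 call of 21, with 20 not called, and 3 rose and 4 fell when adjusted over the list alone. Of 24 glycolysis and hypoxia genes, Vegfa, an angiogenic growth factor, rose 3.46-fold, 0 fell and 23 were not called, with 3 rises when adjusted over the list alone (median 0.05, range −0.02 to 0.20, camera adjusted p = 0.102, and 0.0496 without DEM replicate 1). Cholangiocyte markers were shifted downward (median −0.28 over 4 genes, camera adjusted p = 0.0484, and adjusted p = 0.504 with an estimated correlation) with 0 of 4 called and 1 lower when adjusted over the list alone, and the bile duct transcription factor gene Sox9 had a log2 change of −0.69 ± 0.11. That list lost its call without DEM replicate 1 (camera adjusted p = 0.0538), DEM replicate 2 (0.0737) or DMSO replicate 1 (0.120), and its median was −0.18 without DMSO replicate 1 and −0.45 without DMSO replicate 2.

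In the other lists limma called 0 genes over all genes tested and camera did not pass the threshold. The 34 cell cycle genes had a median of −0.10 (2 lower at an unadjusted p under 0.05; Ccne2, a cyclin, −0.33 ± 0.12; camera adjusted p = 0.0550), which ran from −0.17 to 0.05 over the alternatives, and the list passed without DMSO replicate 2 (0.00938). The 21 cholesterol synthesis genes had a median of −0.09 (3 lower at an unadjusted p under 0.05; Dhcr7, the last enzyme of the pathway, −0.58 ± 0.16; range −0.21 to 0.06). The 15 fatty acid synthesis genes had a median of −0.02 (1 lower at an unadjusted p under 0.05; Acacb, an acetyl-CoA carboxylase, −0.66 ± 0.20; range −0.10 to 0.12). None of these 3 lists had a call adjusted over the list alone. The cholesterol synthesis list passed camera without DEM replicate 1 (adjusted p = 0.00979) or DMSO replicate 2 (0.0268), and the targets of the aryl hydrocarbon receptor without DEM replicate 1 (0.0288). Of the 36 hepatocyte genes listed, 10 were tested, 23 were not well above background on at least 2 arrays and 3 had no named probe. Of the 10 tested, 3 were higher when adjusted over the list alone and 4 higher and 1 lower at an unadjusted p under 0.05 (median 0.14, range −0.04 to 0.31). Apob, the main protein of very low density lipoprotein, had a log2 change of 3.45 ± 0.80 (limma adjusted p = 0.138; 0.85 after normexp), well above background on 1 of the 2 DMSO arrays. Of 5 metal response genes, 2 were higher and 1 lower both when adjusted over the list alone and at an unadjusted p under 0.05 (median 0.57, range −0.20 to 0.81). The metallothionein gene Mt2 had a log2 change of 1.11 ± 0.20 (limma adjusted p = 0.0883). The 5 targets of the aryl hydrocarbon receptor (median 0.19, range −0.07 to 0.43; Ahr, the receptor itself, 0.28 ± 0.16), the 8 fibroblast and stellate markers (median −0.07, range −0.15 to 0.07; Pdgfrb, a growth factor receptor, 0.27 ± 0.11) and the 3 endothelial markers (median −0.12, range −0.20 to 0.02; Lyve1, a hyaluronan receptor, −0.19 ± 0.09) had 0 calls adjusted over the list alone and 0, 1 and 0 genes at an unadjusted p under 0.05. Over all 26 lists, 12 passed with the preset correlation, 0 with an estimated one (1 at an unadjusted p under 0.05) and 1, the chaperones of the endoplasmic reticulum, by fry (adjusted p = 0.00343; 11 at an unadjusted p under 0.05).

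Genes seen in 1 group alone made up 35 calls, 19 higher in DEM with no probe well above background in DMSO and 16 lower in DEM with none well above background in DEM. The largest bounds, after Gsta1, were Wbscr25 at least 5.27-fold, the transcripts ENSMUST00000101159 at least 5.11-fold and ENSMUST00000118321 at least 4.95-fold, and Gsta2 at least 4.15-fold higher. Their limma adjusted p (Benjamini-Hochberg) lay between 0.00442 and 0.0495. After normexp, whose offset shrinks dim changes by construction, the log2 changes of these 5 genes were 0.79 to 1.46. Of the 35 calls 18 passed the threshold after normexp, against 135 of the 149 calls well above background on all 4 arrays. ENSMUST00000101159 and ENSMUST00000118321 had the same log2 signals in DMSO (−7.56 and −7.73), which may be a floor value of each array, so their adjusted p may not rest on a measured spread. In DEM replicates 1 and 2 they lay at −2.26 and −3.75, and at −2.37 and −3.73. Whether they are 1 signal under 2 names was not tested.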

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

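Scaling on spike-in probes was the 1 alternative chosen after seeing the data. By the probe used for each gene, no gene called in the main comparison changed sign under any alternative. Leaving out an array could not turn a sign, since the groups of all 190 called genes did not overlap. With every probe on its own, 1 of 36 called genes with more than 1 tested probe had a probe of the other sign. The log2 changes of Slc7a11 and Hmox1 ran from 3.73 to 5.29 and from 4.44 to 4.70 over 16 alternatives. Depending on the setting, the number of calls differed widely; the cause was not tested unless stated. Normexp called 437 higher and 370 lower genes (52 and 32 by at least 2-fold) and kept 157 of the 190 calls. Quantile normalization called 61 and 32 (27 lower by at least 2-fold) and kept 93. Median scaling called 404 and 163 (176 and 86). Spike-in scaling called 198 and 370 (145 and 249), with infinite prior degrees of freedom. An intensity trend gave 415 and 311 (94 lower by at least 2-fold), and with robust fitting 492 and 390 (104). A filter on all 4 arrays gave 230 and 196 among fewer genes. With no filter on dim probes limma called 0 genes of 32288, with 1246 higher and 1919 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.105. Every probe on its own gave 109 and 78, and the mean of a gene's probes 109 and 81. The value table, equal to the processed signal, moved nothing, and a slide block could not be run on 1 slide. Leaving out an array, which leaves a lone sample assumed to vary like the other group, gave 0 to 69 higher and 0 to 52 lower genes, each by at least 2-fold. With only a replicate number shared, the replicate block in a paired fit gave 74 higher and 69 lower genes and kept 99 of the calls. Same-numbered samples deviated from their group means with a correlation of 0.14 across genes. That value does not exclude a pairing. With the block, 1961 genes were higher and 2340 lower at an unadjusted p under 0.05, against 1401 and 1587 without it. Saa3, picked by hand, had log2 signals of −1.92 and −3.73 in DEM replicates 1 and 2, and −1.89 and −3.68 in DMSO replicates 1 and 2. How many genes behave so was not counted, and the main fit ignores any such pairing.

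For the lists, an estimated correlation called 0 of 26 and fry 1. The adjusted p of the 12 called lists was 0.504 with an estimated correlation for glutathione synthesis, NADPH, phase II, haem and iron, heat shock, endoplasmic reticulum chaperones, p53 targets, NF-kB and cholangiocyte markers, 0.580 for ATF4 targets, and 0.593 for proteasome and autophagy. By fry it was 0.0754 for glutathione synthesis, 0.0734 for NADPH and for haem and iron, 0.0886 for phase II, heat shock and cholangiocyte markers, 0.0973 for NF-kB, 0.112 for p53 targets, 0.124 for ATF4 targets, 0.266 for proteasome and 0.321 for autophagy; fry does not compare a list with other genes. With the preset correlation, glutathione synthesis, NADPH, phase II, haem and iron, heat shock, ATF4 targets, p53 targets and NF-kB passed under 16 of 16 alternatives, with a highest camera adjusted p of 0.00963, for p53 targets. Camera adjusted p under the other settings was as follows. After normexp it was 0.0234 for thioredoxin, 0.0424 for ABC transporters, 0.0113 for NRF2 and its regulators, 0.0195 for glycolysis and hypoxia and 0.0527 for cholangiocyte markers, and fatty acid synthesis turned upward by camera at 0.738 while its median stayed at −0.04. Under spike-in scaling proteasome (0.178), endoplasmic reticulum chaperones (0.144), autophagy (0.159) and cholangiocyte markers (0.144) lost the call, hepatocyte genes gained it (0.00135) and immediate early genes turned (0.499). Fatty acid synthesis turned under median scaling (0.943). Quantile normalization gave 0.00433 for cell cycle genes. With no filter, NRF2 and its regulators gave 0.0456, cell cycle 0.0140, cholesterol synthesis 0.0293 and cholangiocyte markers 0.0599. With the filter on all 4 arrays NRF2 and its regulators gave 0.0473 and cell cycle 0.0440, and with the mean of probes NRF2 and its regulators gave 0.0259. The replicate block gave 0.0476 for aryl hydrocarbon receptor targets and 0.0365 for cell cycle genes. Leaving out an array gave 0.0367 to 0.0976 for NRF2 and its regulators, 3.11e-04 to 0.101 for proteasome, 0.0288 to 0.901 for aryl hydrocarbon receptor targets, 0.411 to 0.794 for immediate early genes, 0.00938 to 0.476 for cell cycle, 0.00979 to 0.901 for cholesterol synthesis, 0.445 to 0.629 for fatty acid synthesis, 0.0496 to 0.206 for glycolysis and hypoxia, 0.00179 to 0.248 for autophagy and 0.04998 to 0.120 for cholangiocyte markers; the immediate early list turned without DEM replicate 1, cholesterol synthesis without DEM replicate 2 and fatty acid synthesis without DEM replicate 2 or DMSO replicate 1.

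The log2 change of Nfe2l2, near 0, was −0.00300 after quantile normalization, −0.0275 under spike-in scaling and −0.0323 to 0.127 with an array left out. Of the other values of named genes, 178 lost their call, 23 gained one and 670 kept direction and side of the threshold, with 40 of the losses in each of the settings with no filter, without DMSO replicate 1 and without DMSO replicate 2. Signal over background limits the genes seen in 1 group alone, whose folds are bounds.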

Other observations

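The genes of this part, and the tests of array scaling (for NF-kB and for the clock genes), of short-lived transcripts and of leukocytes, were chosen after their results were seen. Among the called genes outside the fixed lists are single genes known as NF-kB targets or chemokines, picked by hand and not counted against all such genes: Nfkbie, another IkB protein, was 2.18-fold lower in DEM, Tnfaip2 2.02-fold lower, and the chemokine genes Cxcl3 and Ppbp 2.52-fold and 2.13-fold lower. Picked in the same way from genes known to be induced by interferon gamma, Tgtp1 was 2.39-fold, Gbp9 2.30-fold, Gbp3 1.75-fold and Irf8, an interferon regulatory factor, 2.22-fold lower. Pdgfb, a growth factor gene, and Apln, which encodes the peptide hormone apelin, were 2.54-fold and 2.53-fold lower, whereas Il7, a growth factor for lymphocytes, was 3.96-fold higher. Among other rises, Entpd5, an endoplasmic reticulum nucleotidase, was 3.04-fold higher, Ypel5 2.56-fold and Pir, an iron-binding nuclear protein, 2.25-fold higher. All of these passed an adjusted p of 0.05 (limma, Benjamini-Hochberg; n = 2 arrays per group).

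The fall of the NF-kB and inflammatory list is the pattern that opposes the rises of the antioxidant genes. Camera called it at the preset correlation but not with an estimated one (camera adjusted p = 0.504). Array scaling is argued against, since the highest list median under 3 other scalings and normexp was −0.65. A loss of short-lived transcripts in general predicts a like fall of immediate early genes, whose median was −0.058 with an SD of 0.58. These genes went both ways, with 3 higher and 4 lower when adjusted over the list alone, so rises in some could hide a loss. That comparison therefore cannot decide, and a general loss was left open. Fewer leukocytes in the culture would require leukocytes among cells that the labels name as a hepatoma line. In DMSO the log2 signals of Lyz2, Tyrobp and Ptprc were −5.81, −7.55 and −4.95, against 7.29 for Ccl2, a member of the list. Signals of different probes compare only roughly. In DEM the signals of Lyz2, Tyrobp and Ptprc were −5.66, −7.21 and −7.18, so Ptprc was lower there and the other 2 were not. Of these 3 markers 0 were well above background on both DMSO arrays (Cd68 had no named probe). Lyz2 and Ptprc were well above it on 1 DMSO array each. The markers therefore gave little sign of leukocytes and could not measure a loss, and the lower Ptprc leaves a loss open. The 3 markers that could be tested went both ways, with log2 changes of 0.42 for Csf1r, −0.45 for Cd14 and −0.30 for Cd3e. A lower interferon response stays open, since the median of 26 interferon-stimulated genes was −0.21 (camera p = 0.0134, and p = 0.380 with an estimated correlation). Of the 26, 18 were lower and 0 were called by limma, on a list that leaves out the called Tgtp1, Gbp9, Gbp3 and Irf8. An effect of DEM on NF-kB itself may account for the falls and is a hypothesis that was not tested.

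Calls in genes not well above background in 1 group may rest on an understated spread near the floor. After normexp 51.4% of these 35 calls passed the threshold, against 90.6% of the calls measured on all 4 arrays. Normexp adds an offset of 50 to arrays whose median signal was 16.2 to 18.6, so it shrinks the changes of dim genes by construction, and the lower share says little about their spread. The floor and a true change in these genes cannot be told apart with this test and 2 arrays per group.

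Of the genes of the circadian clock, Nr1d1 and Bhlhe40 were 2.43-fold and 2.32-fold lower in DEM and Per2, not well above background in DEM, at least 1.78-fold lower. The other clock genes driven by E-boxes did not fall as a set, since the median of the 8 tested was 0.13 with an SD of 0.19 (0 called by limma). That list leaves out the 3 genes, which were picked after their falls were seen, and only 1 time was measured. The comparison therefore cannot decide whether the output of the clock was lower. Array scaling is argued against, since the highest median of the 3 genes was −1.14 under 3 other scalings and −0.88 after normexp, a background correction that shrinks dim changes. Whether these 3 genes responded to DEM through the clock or apart from it was not tested.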
